A study of Mus musculus with 6 samples.

How the data were processed

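The 6 samples were auditory nerves microdissected from mouse cochleas, 3 from wildtype mice and 3 from mice with a knockout of Cfb, with the 2 cochleas of 1 mouse pooled per sample. Per the labels' protocols, total RNA was purified with the miRNeasy kit, samples of low quality on a Bioanalyzer were excluded, and libraries were made with Illumina's TruSeq RNA kit. TopHat2, DESeq2, Partek and the build mm10 are named in the submitters' processing notes, without versions or roles. The annotation release, the filters, the strand setting and the sequencing depth were not given in the sources used here.

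The deposited table holds 1 value per gene and sample, a score that the authors made: gene counts scaled per sample and rounded to whole numbers, called normalized counts here. This reading comes from the values. The median-of-ratios factors of the columns were between 1.0038 and 1.0068, and for 99.9% of 13938 genes with both means over 50 the deposited fold change lay within 1% of the ratio of the column means. The number of low whole values that no gene had was 2, 3 and 1 in knockout replicate 1, 2 and 3, and the number of low whole values held by an excess of genes was 1, 5 and 2 in wildtype replicate 1, 2 and 3, as rounding after scaling leaves them. The first number was 0 in each library labelled wildtype, and the second was 0 in each library labelled knockout. Scaling up leaves values that no gene has, and scaling down leaves values held by an excess of genes. The whole reads were not recovered, so no count test was run, although the design fixed before the data were examined had named one for raw counts. The fallback fixed with it, limma on log values, was used. The table also holds the authors' signed fold change and false discovery rate of knockout against wildtype, per the file headers; 2061 genes have no rate. There were 0 columns of sample values left unused. Column totals were 40014927, 38675077 and 41496282 in the libraries labelled wildtype and 39599210, 40918311 and 40448250 in those labelled knockout; these are normalized totals. No 2 libraries agreed within sampling noise: the chi-square per gene between pairs was 24.3 or more over genes with a mean of at least 20, so the 6 libraries were counted as separate. Pairs of libraries labelled knockout had 24.3 to 32.2, and pairs labelled wildtype had 71.4 to 288. The libraries labelled wildtype thus differed more from one another, and limma pooled the spread of both labels.

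Values were transformed as log2(value + 1), and genes with a mean of at least 1 were kept, a filter that removed 0 genes of 17666. The fold changes are on this log2(value + 1) scale, which understates the change of low genes. Limma 3.58.1 in R 4.3.3 fitted label as the only term, with eBayes and a trend on the mean, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 of 29 lists with at least 5 measured members. None of the calls of camera held with an estimated correlation. Fry was an alternative; it tests whether the genes of a set move on balance one way and does not compare the set with other genes. The genes around Cfb were tested with Fisher's exact test, two-sided. With 3 samples against 3, an exact permutation test of 1 value could not give a p below 0.1.

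The lists were fixed before the data were examined: complement, genes around Cfb, macrophage, peripheral myelin, non-myelinating glia, central glia, spiral ganglion neuron, synaptic vesicle, node of Ranvier, organ of Corti, lateral wall, osteoblast, osteoclast, fibroblast and matrix, endothelial, mural, red cell, neutrophil and marrow, lymphocyte, skeletal muscle, interferon, cytokine, immediate early, cell cycle, cholesterol, mitochondrial, ribosomal protein, sex-linked and respiratory chain. The tests, the alternatives and the rule for named genes were fixed then too. The rule names Cfb and C2, then up to 12 genes with the largest rise and 12 with the largest fall among genes past the threshold whose values did not overlap between labels. Symbols that only number a gene model and receptor segments of lymphocytes were left out. In each list it names up to 4 members past the threshold or, with none, the 2 with the highest mean. Members called in the authors' deposited table were named by the same rule, a choice made after the data were examined. Glo1, Tyr, other members counted in the text in groups of 5 or fewer, and the copies of called genes were not named by the rule and were chosen after their values were seen. Some genes that the rule names are not reported here.

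On simulated data with the means and spread of these samples, limma recovered 51 of 100 genes changed 2-fold and 82 of 100 changed 4-fold, with 5 false calls among 138 over 17619 genes. The list test found a shifted list and called 3 of 100 unshifted lists at 0.05. Genes were simulated independently of one another, so this error rate does not cover lists with correlated members. In these samples the estimated correlation reached 0.683, in the ribosomal protein list. Coordinates come from a RefSeq gene table of the mm10 assembly; 17264 symbols matched directly and 364 through 1 synonym. Transcript length and GC content come from GENCODE M21, with a length for 98.9% of genes. Random sets of genes and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alternatives covered the pseudocount (0.1 and 5), a mean of at least 10, array weights, median centring, a replicate block, an osteoblast covariate, each library left out, stricter thresholds, and, added after the data were examined, voom weights and a correction for transcript length.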

Results

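RNA sequencing measured the transcripts of the auditory nerve in young adult mice aged 1.5 to 2.5 months. The comparison asked how the nerve differs between wildtype mice and mice with a knockout of Cfb, the gene of complement factor B, a serine protease of the alternative complement pathway. There were 3 samples of each genotype, and each sample was the nerve tissue microdissected from the 2 cochleas of 1 mouse. The table listed 17666 genes with a normalized count for each sample. The normalized counts of a sample summed to between 38675077 and 41496282. These totals were set by the scaling, so the number of reads of each sample is unknown. The gaps and excesses among low values point to scaling up in the libraries labelled knockout and scaling down in the others. Depth may therefore go with the label, and its effects cannot be told apart from those of the genotype.

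Cfb, the targeted gene (chromosome 17, 34856374 to 34862514, mm10), went against the labels. Its normalized counts were 55, 39 and 116 in the libraries labelled wildtype and 336, 351 and 376 in the libraries labelled knockout. The means were 70.0 ± 40.6 and 354.3 ± 20.2 (SD, n = 3 each), a 5.06-fold higher level in the libraries labelled knockout. The log2 fold change was 2.47 with a standard error of 0.38, and its adjusted p of 0.107 by limma did not pass the threshold of 0.05. Without wildtype replicate 3 it did, with a log2 fold change of 2.91 and an adjusted p of 0.00348, the lowest of a range that reached 0.470 over the alternatives. In the authors' deposited table the fold change of Cfb was 5.08 with a false discovery rate of 1.8e-06. A count per gene does not show which part of the gene the reads came from, so it could not be checked whether they lie within the disrupted part. All directions below are therefore between libraries as labelled. C2, the neighbouring complement gene, had means of 1425 ± 711 and 1418 ± 139 (SD, n = 3 each), a difference within the spread between replicates (adjusted p = 0.890).

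**Figure D1:**
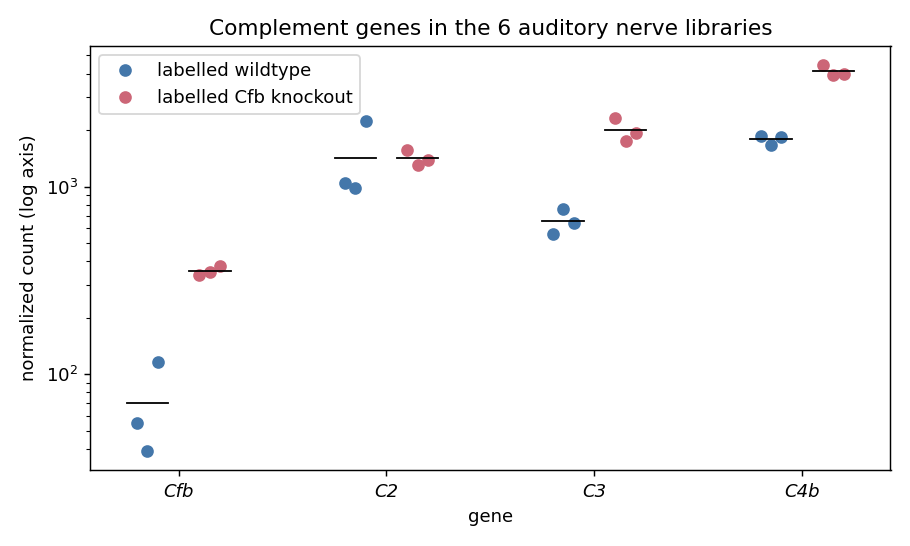
Normalized counts on a log axis of Cfb, C2, C3 and C4b in each of the 6 libraries, with a line at the mean of each label (3 libraries). The Cfb values of the libraries labelled knockout lie between 336 and 376, above the 39 to 116 of the libraries labelled wildtype, and the C2 values of the labels overlap.

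Among the genes that passed the test were 2 further complement genes. C3, the central component of complement, rose 3.07-fold in the libraries labelled knockout, from 652.7 ± 99.9 to 2004 ± 294 normalized counts (SD, n = 3 each). C4b, a component of the classical pathway, rose 2.30-fold, from 1787 ± 102 to 4113 ± 275. Both genes lie on chromosome 17, as Cfb does, with C4b starting at 34.7 Mb and C3 at 57.2 Mb. Whether sequence linked to Cfb accounts for their rise was not tested. Fgf21, a metabolic hormone, rose from 19.7 ± 13.4 to 234.0 ± 4.6, and Dock2, an activator of Rac in blood cells, from 33.0 ± 7.0 to 218.7 ± 24.6. Atp6v0c, a subunit of the vacuolar proton pump, fell 3.56-fold, from 15284 ± 1131 to 4297 ± 223. Samd11 fell 13.1-fold, from 328.7 ± 104.5 to 25.0 ± 9.5.

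By limma, 28 of 17666 genes passed an adjusted p of 0.05, of which 18 rose and 10 fell in the libraries labelled knockout. The log2 fold change was 1.62 for C3 (SE 0.16, adjusted p = 0.0297) and 1.20 for C4b (SE 0.10, adjusted p = 0.0214). It was 3.70 for Fgf21 (SE 0.44, adjusted p = 0.0409; 4.19 without wildtype replicate 1) and 2.71 for Dock2 (SE 0.24, adjusted p = 0.0258). For Atp6v0c it was -1.83 (SE 0.11, adjusted p = 0.00616) and for Samd11 -3.69 (SE 0.38, adjusted p = 0.0297). Further rises were in Gucy2c (4.21), a receptor guanylate cyclase, Pi16 (2.14), Adgrv1 (1.67), an adhesion receptor of the hair cell bundle, Plekhn1 (1.61), Fam234b (1.53) and Tspan11 (1.49). Further falls were in Lyplal1 (-1.56), Ppil1 (-1.55), H2-M3 (-1.55), Wdfy1 (-1.43) and Decr2 (-1.08). Klrb1b was listed at 0 in the 3 libraries labelled wildtype and at 17, 18 and 22 in the others. Peg3os was listed at 317, 403 and 40 in the libraries labelled wildtype and at 0 in the others. Glo1 (0.87), which detoxifies methylglyoxal, and gene models that carry numbers as names were also called, all of these higher in the libraries labelled knockout; the other called genes follow with their copies.

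Several called genes have near-identical copies or overlap another gene, and their values are uncertain where reads could be divided between copies. Atp6v0c fell while its processed pseudogene Atp6v0c-ps2 rose (log2 fold change 2.28). Their sum was 16494 ± 1307 in the libraries labelled wildtype and 9947 ± 953 in the others (SD, n = 3 each). Hmga1b fell (-1.89), and Hmga1, with 1657 and 1269 normalized counts on average, did not pass (adjusted p = 0.210). C4a, the close copy of C4b, had 45.7 and 60.7 normalized counts on average. H2-T9 (-5.18, and -5.68 without knockout replicate 2) belongs to the class I histocompatibility family, and Peg3os is an antisense transcript. Strand use in the counting was not given in the sources used here.

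After a correction for transcript length, C3 (1.44, adjusted p = 0.0684), Fgf21 (3.97, adjusted p = 0.0526), Adgrv1 (0.67, adjusted p = 0.250) and Tspan11 (1.31, adjusted p = 0.0510) no longer passed. The number of calls depended on single libraries. Limma called 0 genes without any one of the libraries labelled knockout, with 2218, 1797 and 1892 genes at an unadjusted p under 0.05 without replicate 1, 2 and 3, and called 87, 2 and 566 genes without wildtype replicate 1, 2 and 3. By the false discovery rate of the authors' deposited table, under 0.05 for 1153 genes, 646 were higher and 507 lower in the libraries labelled knockout, and 27 of the 28 genes called by limma were among them. The remaining gene, Klrb1b, had no rate in the authors' deposited table.

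**Figure D2:**
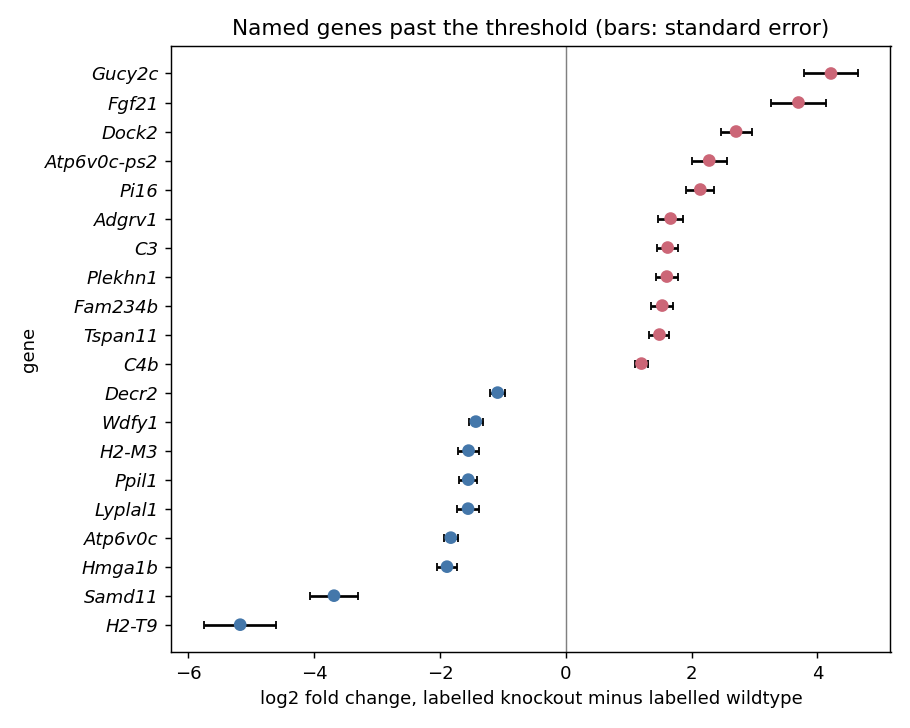
Log2 fold change (libraries labelled knockout minus libraries labelled wildtype, 3 each) of the named genes past the threshold, with bars of 1 standard error, leaving out Klrb1b and Peg3os, which were listed at 0 in every library of 1 label. Values run from -5.18 for H2-T9 to 4.21 for Gucy2c.

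Genes around Cfb were looked at separately because a targeted allele can carry flanking sequence of another strain. Of 78 tested genes on the fixed list around Cfb, Cfb left out, C4b was the 1 gene called, against 27 of 17587 other genes (odds ratio 8.44, 95% interval 0.204 to 52.6, Fisher's exact test, two-sided, p = 0.117). The list does not hold every gene of the histocompatibility region. The called genes Gm8801 (35.9 Mb) and H2-M3 (37.3 Mb) of chromosome 17, and H2-T9, were counted among the other genes. When adjusted over the list alone, 4 genes passed, all higher: C4b, Tnxb, Prrc2a and Vars. The same 4 genes were called in the authors' deposited table, which was 5.13% of the list against 6.53% of other genes. Within 15 Mb of Cfb, a window chosen after the results were seen, the authors' deposited table called 11.4% of 546 genes, against 6.35% elsewhere. The list median was -0.03 on the log2 scale, and the list was not called as a set (adjusted p = 0.743); after a correction for transcript length its median was 0.10 and it was called as higher (adjusted p = 0.0131).

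**Figure D3:**
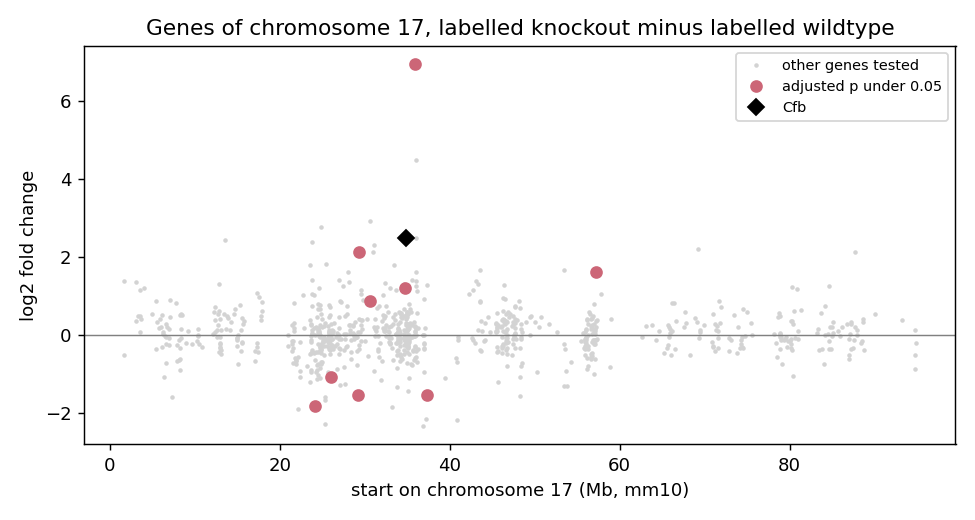
Log2 fold change (libraries labelled knockout minus libraries labelled wildtype) of each tested gene of chromosome 17 by its start in Mb (mm10). The 9 called genes are drawn large, 8 of them within 15 Mb of Cfb, and the other is C3 at 57.2 Mb. The highest point is Gm8801, listed at 0, 1 and 0 in the libraries labelled wildtype, so that its height depends on the pseudocount.

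In the gene lists, members given as a log2 difference alone did not pass over all genes by limma, and several of these differences moved by over 1.5 times without 1 library, most often wildtype replicate 3. Over all 17666 genes, 3529 had an unadjusted p under 0.05 by limma, and the authors' deposited table called 1153. Counts of list members at an unadjusted p under 0.05, or called by the authors, are to be read against these shares. Among 35 measured complement genes other than Cfb, C3 and C4b rose and 33 did not pass; adjusted over the list alone, Itgam (0.61), a subunit of complement receptor 3, passed too. Itgam was 1.52-fold higher in the authors' deposited table and Cd59a, an inhibitor of the membrane attack complex, 1.36-fold lower. The list was not called as a set (adjusted p = 0.853). No member of the macrophage, interferon or cytokine lists passed by limma over all genes, with 5, 4 and 4 members at an unadjusted p under 0.05. In each of these lists that was below the share over all genes. Of 28 macrophage genes, the abundant receptor gene Csf1r had a log2 difference of 0.17, and in the authors' deposited table Cd74 was 1.39-fold higher and Cd86 1.99-fold lower. Of 28 interferon-stimulated genes, the abundant Ifi27 had a difference of -0.54 (-0.26 without wildtype replicate 3), and in the authors' deposited table Stat2 was 1.44-fold higher. Of 24 cytokine genes, Il34 (-0.75) and Cxcl13 (-2.73) passed when adjusted over the list alone, and in the authors' deposited table Il34, Cxcl13 and Vcam1 were lower by 1.69-, 7.65- and 2.74-fold. Vcam1 and Cxcl12, the most abundant members, had differences of -1.27 and 0.09, and without wildtype replicate 3, which had 11065 normalized counts of Vcam1, the former was -0.77. None of these 3 lists was called as a set (adjusted p = 0.280, 0.853 and 0.853).

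Red cell and marrow transcripts were lower in the libraries labelled knockout. The red cell list was called as a set by camera (median log2 difference -2.19, adjusted p = 3.13e-08), and so was the neutrophil and marrow list (median -2.11, adjusted p = 3.53e-07). Neither call held for the list as a whole with correlated members (adjusted p = 0.748 with an estimated correlation for each). No single member passed over all genes by limma, with 13 in each list at an unadjusted p under 0.05. Of the red cell genes, adjusted over the list alone, 12 of 19 were lower and 1, Sptb, higher, and Mmp8, S100a9, Camp and Mpo were lower among 20 marrow genes. Hbb-b2 and Hbb-bt had identical means, SDs and p-values. The same measurement may thus be counted under both names, here and among the authors' calls. The authors' deposited table called 9 red cell genes, all lower, among them the globins Hba-a1 (4.55-fold) and Hbb-b1 (6.34-fold), whose reads could be divided between close copies. It also called the marrow genes Mmp8, S100a9, Camp, Mpo and Ngp, all lower. The most abundant members were Tfrc (-0.35) and Sptb (0.80) in the red cell list and Ltf and S100a9 (-3.02) in the marrow list. Ltf had 103, 103 and 534 normalized counts in the libraries labelled wildtype and 460, 61 and 1 in the others, which overlap, and its log2 difference of -2.22 was -0.087 without knockout replicate 3. Without wildtype replicate 3 the log2 difference of Hbb-b1 went from -2.44 to -1.85. The lymphocyte list had a median of -0.56 (adjusted p = 0.0246, and adjusted p = 0.748 with an estimated correlation), and Ebf1 and Blnk, its most abundant members, had differences of 0.02 and -0.20; no member passed by limma (5 at an unadjusted p under 0.05) or in the authors' deposited table. Wildtype replicate 3 had the highest levels of all 3 lists, with a mean deviation of 2.03 for the red cell list. Without it the medians were -1.60, -1.66 and -0.31 and the lymphocyte list was no longer called (adjusted p = 0.323). Knockout replicate 3 had the lowest marrow level, with a mean deviation of -2.51, and without it the marrow median was -1.37 and the lymphocyte median -0.22, and without knockout replicate 1 the lymphocyte median was -0.29, each list still called.

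Neuronal lists lay higher in the libraries labelled knockout by the set test, and no member passed over all genes by limma, with 8, 8 and 9 members of the 3 lists at an unadjusted p under 0.05. For the spiral ganglion neuron list, 8 of 40 was near the share over all genes, 3529 of 17666. The spiral ganglion neuron list (40 genes, median 0.30, adjusted p = 0.0125), the synaptic vesicle list (24 genes, median 0.29, adjusted p = 0.00337) and the node of Ranvier list (22 genes, median 0.48, adjusted p = 3.78e-05) were called, with adjusted p = 0.748 with an estimated correlation for each. By the authors' deposited table the transcription factor gene Prox1 was 1.72-fold, Map2 1.46-fold and the potassium channel gene Kcna1 1.39-fold higher. The presynaptic genes Bsn, Pclo and Sv2c were 2.30-, 1.92- and 2.58-fold higher in the authors' deposited table. Calb2 and Snap25, the most abundant neuronal genes, had log2 differences of -0.15 and -0.12, Vamp1 -0.01 and Kcna2 0.59; without wildtype replicate 3 the 4 differences were -0.28, -0.47, -0.28 and 0.38. Wildtype replicate 3 had the lowest mean deviation in these lists (-0.61, -0.76 and -0.60). Without it the neuronal and synaptic lists were no longer called (medians 0.06 and 0.07, adjusted p = 0.786 and 0.605), and the node list had a median of 0.34 (adjusted p = 0.0128), while without wildtype replicate 1 the neuronal and synaptic medians were 0.51 and 0.54. After a correction for transcript length the neuronal list was not called (median 0.10, adjusted p = 0.1004), and the synaptic and node medians were 0.18 and 0.21 (adjusted p = 0.0370 and 0.0190).

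The peripheral myelin list was lower in the libraries labelled knockout by the set test (23 genes, median -0.21, adjusted p = 0.0125, and adjusted p = 0.748 with an estimated correlation). Ncmap, Pmp22, Mal and Cd9 were lower when adjusted over the list alone, and 0 members passed over all genes by limma, with 5 at an unadjusted p under 0.05. The authors' deposited table called the same 4 genes, lower by 1.58-, 1.69-, 1.61- and 1.61-fold. Without wildtype replicate 1 or 2 the list was not called (medians -0.17 and -0.10, adjusted p = 0.0891 and 0.0937), and without wildtype replicate 3 its median was -0.44 (adjusted p = 4.81e-05). Pmp22, a structural protein of peripheral myelin, had 69615 ± 6726 normalized counts in the libraries labelled wildtype and 41251 ± 3660 in the others (SD, n = 3 each). Mbp, an abundant member, had a difference of -0.21, within the spread between replicates, and of -0.45 without wildtype replicate 3. The non-myelinating glia list (18 genes, median 0.10, adjusted p = 0.710) and the central glia list (20 genes, median 0.23, adjusted p = 0.280) were not called; without wildtype replicate 2 the latter was called as higher (median 0.37, adjusted p = 0.00336), and without wildtype replicate 3 its median was 0.01 (adjusted p = 0.933). Apoe (-0.18), Gjb6 (-0.32) and Gfap (0.69) were among their most abundant members, with -0.050, 0.10 and 0.41 without wildtype replicate 3. By the authors' deposited table Cdh19 was 1.31-fold lower and Cspg4 1.84-fold higher.

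Transcripts of the organ of Corti, the sensory epithelium next to the nerve, lay higher in the libraries labelled knockout (30 genes, median 0.80, adjusted p = 5.38e-04, and adjusted p = 0.748 with an estimated correlation). No member passed by limma, with 10 at an unadjusted p under 0.05, and the authors' deposited table called the hair bundle genes Cdh23 and Loxhd1 and the tectorial membrane genes Otog, Tecta and Tectb, all higher, with folds of 2.11, 5.13, 3.63, 12.1 and 3.08. Tecta had 866, 1611 and 84 normalized counts in the libraries labelled knockout, so knockout replicate 3 lay near the 63 to 86 of the other label. In knockout replicate 3, Otog had 4781, below the 5163 of wildtype replicate 3. Loxhd1 had 345 there and Tectb 242, close to the highest wildtype values of 341 and 208, while Cdh23 had 1287 against 854. The mean deviation of the list was -0.06 in knockout replicate 3, below the 0.42 of wildtype replicate 3. Without knockout replicate 2 the log2 difference of Tecta went from 2.79 to 1.93, and without wildtype replicate 3 those of Otog and Loxhd1 went from 1.87 and 2.57 to 2.36 and 3.28. Gjb6 and Ceacam16, the most abundant members, had differences of -0.32 and 0.23, and of 0.10 and 0.68 without wildtype replicate 3. The lateral wall list, of stria vascularis, pigment cells and fibrocytes of the spiral ligament, had a median of -0.56 (17 genes, adjusted p = 0.0168, and adjusted p = 0.748 with an estimated correlation), with the fibrocyte genes Coch at -0.38 and Otos at -0.26. Wildtype replicate 3 stood apart there: Tyr, the pigment enzyme, had 3775 normalized counts in it against 3 and 268 in the other libraries labelled wildtype. Without wildtype replicate 3 the lateral wall median was 0.07 (adjusted p = 0.947), Coch was at -0.15 and Otos at 0.11, and the median of the organ of Corti was 1.32; the latter was 0.36 without wildtype replicate 2 (adjusted p = 0.0168) and 0.68 without wildtype replicate 1, where it missed the threshold (adjusted p = 0.0503). Without wildtype replicate 1 the lateral wall median was -0.88. No lateral wall gene passed by limma (3 at an unadjusted p under 0.05) or in the authors' deposited table.

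**Figure D4:**
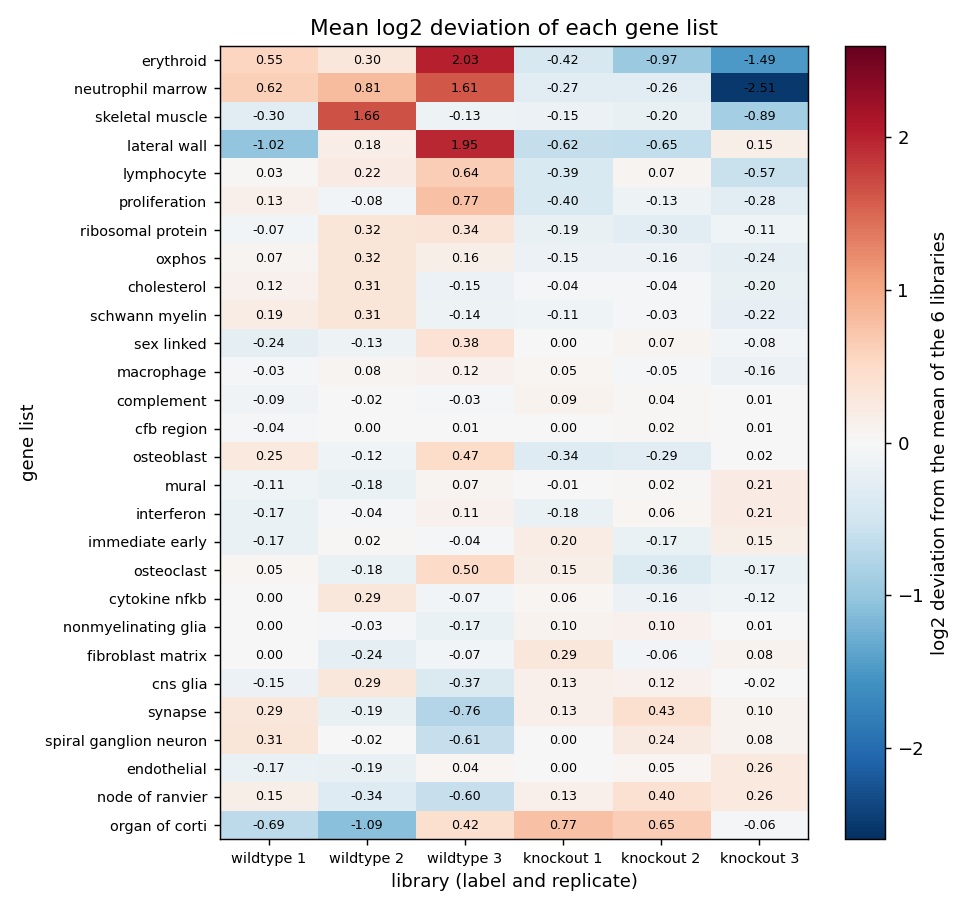
Mean over the members of each gene list of the log2 deviation of a library from the mean of the 6 libraries, with libraries in columns and lists in rows. Wildtype replicate 3 has deviations of 2.03 for the red cell list and 1.95 for the lateral wall list, and wildtype replicate 2 has 1.66 for the skeletal muscle list.

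No endothelial, matrix or mural gene passed over all genes by limma, with 10, 11 and 4 members at an unadjusted p under 0.05. The endothelial list (18 genes, median 0.36, adjusted p = 0.0246) and the fibroblast and matrix list (27 genes, median 0.15, adjusted p = 0.0254) were called as higher sets, with adjusted p = 0.748 with an estimated correlation for each. Of their members, adjusted over the list alone, 6 endothelial genes were higher and 1 lower, and 6 matrix genes were higher and 2 lower. Flt1 (2.18-fold), Kdr (1.54-fold), Ptprb (1.76-fold) and Vwf (1.69-fold) were higher in the authors' deposited table and Ly6c1 (2.01-fold) was lower. Of the matrix genes, 6 were higher and 2 lower in the authors' deposited table, among them Col12a1 (2.37-fold higher), Col6a3 (2.15-fold higher) and Ogn (1.64-fold lower). The most abundant members were Slco1a4 (-0.26) and Emcn (-0.40), and Dcn (-0.42) and Col1a2 (-0.01). The fibroblast list was not called without wildtype replicate 2 or 3 or knockout replicate 1 (medians 0.11, 0.23 and 0.17, adjusted p = 0.0980, 0.0888 and 0.135) or after a correction for transcript length, where its median turned to -0.02 (adjusted p = 0.551), and its median was 0.28 without wildtype replicate 1. The endothelial list was not called without wildtype replicate 1 or knockout replicate 3 (medians 0.37 and 0.24, adjusted p = 0.215 and 0.130), and its median was 0.22 after the length correction (adjusted p = 0.0185). The mural list was not called (14 genes, median 0.02, adjusted p = 0.451); Notch3, Cspg4 and Pdgfrb passed as higher when adjusted over the list alone, and in the authors' deposited table they were 2.04-, 1.84- and 1.55-fold higher. Rgs5 (-0.20, and -0.061 without wildtype replicate 3) was the most abundant mural gene. The osteoblast (20 genes, median 0.01, adjusted p = 0.131) and osteoclast lists (9 genes, median 0.06, adjusted p = 0.853) were not called, and no member passed over all genes by limma, with 6 and 2 at an unadjusted p under 0.05. Bglap and Bglap2 were lower and Itgb3 higher when adjusted over the list alone. The authors' deposited table had Bglap, Bglap2, Ibsp and Sparc lower by 4.33-, 4.84-, 2.25- and 2.08-fold and Itgb3 1.55-fold higher. The osteoblast list was called as lower without wildtype replicate 2 or knockout replicate 3 (medians -0.20 and -0.08, adjusted p = 0.0184 and 0.0179). Spp1 (-0.67), Sparc (-0.94), Ctsk (-0.62) and Nfatc1 (0.24) were the most abundant members, with -0.24, -0.55, -0.43 and 0.42 without wildtype replicate 3.

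The skeletal muscle list had a median of -0.97 (19 genes, adjusted p = 0.0168, and adjusted p = 0.748 with an estimated correlation), with members of each sign. No member passed over all genes by limma, with 6 at an unadjusted p under 0.05. When adjusted over the list alone, Ttn (1.40) and Neb (1.73), which encode giant sarcomere proteins, were higher and Tcap, Casq1 and Myl1 were lower. After a correction for transcript length, Ttn turned to -0.23 and Neb had 0.64. By the authors' deposited table Ttn and Neb were 2.61- and 3.17-fold higher, and 5 members were lower: Tcap, Casq1, Myl1, Acta1 and Ckm. Pvalb, the most abundant member, is also a neuronal gene (-0.23, and -0.48 without wildtype replicate 3). Wildtype replicate 2 had a mean deviation of 1.66 in this list, and without it the list was not called (median -0.18, adjusted p = 0.295).

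Ribosomal protein and respiratory chain genes were lower in the libraries labelled knockout by the set test. The ribosomal list had a median of -0.40 (39 genes, adjusted p = 6.94e-11) and the respiratory chain list one of -0.36 (27 genes, adjusted p = 1.13e-09), with adjusted p = 0.748 with an estimated correlation for each. Of the respiratory chain genes, 14 of 27 were lower when adjusted over the list alone, and 0 of 39 ribosomal genes passed. Over all genes 0 members of either list passed by limma, with 17 respiratory chain and 18 ribosomal genes at an unadjusted p under 0.05. The authors' deposited table called 10 respiratory chain genes, all lower, among them Cox7a2 (1.61-fold), Cox8a (1.66-fold) and Sdhb (1.33-fold), and the ribosomal gene Rpl19 was lower (1.43-fold). Atp5b (-0.10), Atp5a1 (-0.21), Rpl4 (-0.27) and Rpl8 (-0.31) were the most abundant members. Over 15155 genes, the log2 difference had a Spearman correlation of 0.477 with transcript length, across genes that are not independent replicates. After a correction for transcript length the ribosomal median was -0.18 (adjusted p = 0.00195) and the respiratory chain median -0.23 (adjusted p = 2.71e-04).

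The cholesterol synthesis list was lower as a set (22 genes, median -0.22, adjusted p = 0.0193), and so was the cell cycle list (24 genes, median -0.49, adjusted p = 0.00323), with adjusted p = 0.748 with an estimated correlation for each. By the authors' deposited table Nsdhl was 1.61-fold lower and Srebf2, the transcription factor of the pathway, 1.37-fold higher, and Pcna was 1.47-fold lower. Hmgcs1 (-0.25, and -0.51 without wildtype replicate 3) was the most abundant cholesterol gene, and Pcna (-0.54) and Mcm2 (-0.01) the most abundant cell cycle genes. Without wildtype replicate 3 the cell cycle list was not called (median -0.19, adjusted p = 0.275), and the cholesterol median was -0.35 (adjusted p = 4.90e-05); the cholesterol list was not called without wildtype replicate 1 or 2 or knockout replicate 3 (medians -0.18, -0.09 and -0.17, adjusted p = 0.0891, 0.232 and 0.103). No member of these lists passed by limma, with 4 and 6 at an unadjusted p under 0.05. The immediate early list was not called (26 genes, median 0.06, adjusted p = 0.496); Egr1 (1.24) passed when adjusted over the list alone, and in the authors' deposited table Egr1 and Fos were 2.42- and 2.34-fold higher. Without knockout replicate 2 the list was called as higher (adjusted p = 0.0486), and without knockout replicate 1 the log2 difference of Fos went from 1.06 to 0.60. Hsph1 (0.20, and 0.082 without wildtype replicate 3) and Jund (-0.12) were its most abundant members, and no member passed over all genes by limma (5 at an unadjusted p under 0.05). The sex-linked list was not called (6 genes, median -0.17, adjusted p = 0.451), except as lower after a correction for transcript length (adjusted p = 0.01998); all 6 libraries had Ddx3y, a gene of the Y chromosome, at 4314 or more normalized counts. No mitochondrially encoded transcript was among the genes listed, so that list had 0 measured members. The median differed in sign from the mean and from the set test for the histocompatibility region, complement, cytokine, osteoblast and osteoclast lists.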

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

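Voom weights, the length correction, the authors' calls around Cfb and the sign check of the authors' listed calls were added after the data were seen. The 28 calls moved to 7 with a replicate block, 111 with array weights, 0 with the osteoblast covariate (3610 genes at an unadjusted p under 0.05 by limma), 13 with voom and array weights together and 2 at an adjusted p under 0.01. Leaving out 1 library each gave 0 to 566 calls, and fewer samples also change the power. The share of higher calls, 64.3%, was 30.8% with voom and array weights and 50% to 82.8% with 1 library left out, and 52.0% after the length correction. Calls among listed genes, 2 here, were 0 with the block, 15 with array weights, 0 with the osteoblast covariate, 1 with voom and array weights, 1 after the length correction, 0 at the stricter threshold and 0 to 42 with 1 library left out. Cfb passed with array weights (log2 fold change 2.73) and ranged from 2.13 to 2.91 with 1 library left out. Called lists, 16 here, were 0 with an estimated correlation, 0 with fry and 10 to 17 with 1 library left out. The odds ratio around Cfb turned to 0.774 with the authors' calls. The authors' 1153 calls became 426 at a false discovery rate under 0.01 and 285 at a fold of at least 2. For these changes the cause was not tested.

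Replicate numbers did not pair the samples: deviations of libraries with the same number correlated at -0.034, 0.0859 and 0.201, and no pairing is given in the labels. The block left 16 lists called.

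Among 128 named genes under the alternatives, 1931 of 2175 values kept their direction and side of the threshold, 158 no longer passed, 43 came to pass and 43 changed sign, none of them past the threshold in either fit. Most of the 128 were not called, and for these the same side means not passing. Of the 22 called genes with names, 0 stayed called without any one library labelled knockout or with the osteoblast covariate. Without wildtype replicate 2 the number was 1, with the replicate block 4, and with array weights or without wildtype replicate 3 22. All 22 called genes with names kept their sign wherever they were tested. The rule took only genes whose values did not overlap between labels. Leaving out a library or changing the pseudocount could therefore not change their sign. With 1 library left out, log2 differences ran from -0.12 to 0.48 for C2, -0.45 to 0.046 for Mbp, -0.65 to 0.10 for Gjb6, -0.47 to 0.071 for Snap25, -0.28 to 0.15 for Vamp1, -0.038 to 0.68 for Ceacam16, -0.57 to 0.11 for Otos, -0.15 to 0.13 for Col1a2, -0.029 to 0.11 for Ebf1, -0.43 to 0.045 for Blnk, -0.34 to 0.35 for Cxcl12, -0.32 to 0.037 for Jund and -0.13 to 0.20 for Mcm2. With the osteoblast covariate they turned to 0.11 for Gjb6, 0.10 for Otos, 0.012 for Rgs5, -0.0073 for Ebf1, -0.57 for Cxcl12 and 0.29 for Mcm2. After the length correction they turned to 0.028 for Calb2, -0.0495 for Kcna2, -0.22 for Ebf1, 0.034 for Pvalb, -0.23 for Ttn, -0.12 for Cxcl12, 0.028 for Jund and 0.018 for Atp5b. Array weights turned Ebf1 to -0.019, Cxcl12 to -0.18 and Mcm2 to 0.12, and voom with array weights turned Cxcl12 to -0.0126 and Mcm2 to 0.0274. The cause was not tested.

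All 88 listed genes called in the authors' deposited table kept their sign without wildtype replicate 3. Dropping the filter changed nothing, since it removed 0 genes. Count tests and their scalings and filters were not run because the table holds rounded normalized values; the authors' unadjusted p was not used here, and unmatched random lists applied only to a table without sample values. The unknown depth leaves the counting error of low genes open.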

Other observations

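The tests of Cfb, of sequence around Cfb and of the splits for gene lists were chosen after those results were seen, and so was the list of clock genes. Clock genes are given as values. The circadian repressors Per2, Cry1 and Ciart had log2 differences of -1.04, -0.77 and -1.28 and the output gene Dbp -0.98, while the activators Npas2 and Arntl had 2.00 and 1.12. Other repressors overlapped between labels: Per1 (-0.53), Per3 (-0.35), Cry2 (-0.10), Nr1d1 (0.15), Nfil3 (-0.05), Bhlhe40 (-0.03) and Bhlhe41 (-0.44). The repressor Nr1d2 (-0.40) and the activator Clock (0.33) did not overlap. None passed over all genes by limma (adjusted p = 0.0625 for Per2 and 0.121 for Npas2); the list was written after those 2 were seen. Of the other 18 genes, 6 were under 0.05 when adjusted over the list alone, a count of genes from a list prompted by these data, and 9 had values that did not overlap between labels, where chance gives 10% and 28.5% of all genes did so. The time of day of tissue collection was not given in the sources used here.

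The real split gave 28 called genes and 16 called lists. Of the 10 splits of the 6 libraries, 1 gave as many genes and 1 as many lists, the real one in each case; the highest of the others were 0 genes and 13 lists. With 10 splits no share under 0.05 can be reached.

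Cfb was higher in the libraries labelled knockout. Reads of C2 counted to Cfb at a fixed share would keep the ratio of Cfb to C2 alike, and the lowest ratio in the libraries labelled knockout was 4.07 times the highest in the others. An exchange of the labels between all 6 libraries may account for the direction, and it cannot be told apart from a disrupted gene whose transcript is still made, since the lowest Cfb value was 39 and no label was at 0. A general inflammatory response stays open too: the higher of the interferon and cytokine medians was 0.0851, with members moving both ways by more than that (SD 0.406 and 0.799). Neither a changed regulation of Cfb nor the part of the gene read was tested.

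Called genes lay close together on chromosomes. The 27 called genes with a position formed 17 pairs within 5 Mb, against 1.95 on average in random sets, and the most in any of 10000 sets was 11, so that the share with as many, the real set counted in, was 0.01%, the smallest they can give. Leaving out numbered models and pairs of one family the share was 0.02%, which argues against families as the whole cause. Of the 10 splits of the libraries 1, the real one, had as many close pairs among its top genes (highest other 9). The other splits mix the labels, so neighbours that respond together to the genotype would also group in the real split alone. Shared regulation of neighbours therefore stays open. Sequence of another strain kept around Cfb may account for the calls near it, since 1.47% of genes within 15 Mb were called against 0.111% elsewhere, but it cannot be told apart from an effect of the genotype, which goes with it in every library. Sequence around Cfb does not reach calls on other chromosomes, which also lay close together (a share of 0.11%). This speaks only to sequence around Cfb. Whether the labels also differ in strain sequence on other chromosomes was not tested and stays open. The share of 0.11% was counted with numbered models and families kept in, and the share without them was not computed. The 6 close pairs on other chromosomes included Gm10220 with its copy 5031410I06Rik, and Gm10560 with Plekhn1 and with Samd11.

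Short transcripts were lower and long ones higher in the libraries labelled knockout, with medians from -0.26 in the shortest sixth to 0.32 in the longest. Wildtype replicate 3 did not carry this, since the Spearman correlation with length was 0.464 without it against 0.477 with it. No other library was left out for this check, wildtype replicate 2 included, whose correlation of -0.51 was the strongest of its label. GC content did not account for it (partial correlation with length 0.540). Whether length bias could account for the lower ribosomal and respiratory chain lists cannot be told apart from a change in those genes: 99.4% and 96.25% of random lists of like length and level lay above them, and only the first passed the bound set beforehand. Members of the random lists were drawn independently, so their spread is too narrow for lists with correlated members. The estimated correlation was 0.683 in the ribosomal list and 0.276 in the respiratory chain list. By library the correlation was -0.01, -0.51 and -0.19 for the libraries labelled wildtype and 0.38, 0.38 and 0.40 for the others.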
